A study of Rattus norvegicus with 6 samples.

How the data were processed

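Total RNA from primary rat articular cartilage superficial layer cells was extracted with Trizol and made into stranded mRNA libraries, per the labels' protocols. The 6 libraries fall into 2 groups by their titles, 0 dyne/cm² (static) and 20 dyne/cm² (shear), with 3 libraries each. The authors deposited 1 table of counts for the series, with the gene symbol, the exons' chromosome, start, end and strand, the summed exon length and whole-number counts per gene and library, per the file headers. Its columns were matched to the libraries by the column names that the labels repeat. The table's layout is that of featureCounts. The submitters' processing notes name Trimmomatic 0.36, featureCounts, Subread 1.5.1 and edgeR 3.12.1. The aligner, the genome build, the gene annotation, the strand setting of the counting and the treatment of duplicate reads are not given in the sources used here, so positions are printed as the table gives them, with no build. If strand was not used in counting, reads of genes that overlap on opposite strands cannot be told apart. Among the named genes such overlaps covered at most 3.56% of the exon length (Idi1). How reads that match several copies of a gene were counted is not stated either, and Hspa8 and members of receptor families are therefore uncertain.

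The table holds 32161 genes. In 12 of them the symbol had turned into a calendar date, as spreadsheet programs do; 8 of these were tested, 0 changed, and none is named. Older symbols were matched through a RefSeq list of names. Low counts were mostly even: 71.4% to 72.2% of counts from 1 to 20 were even, against 51.1% to 52.3% of counts over 200, and values of 2 (1301 to 1397 per library) outnumbered values of 1 (404 to 457). Counting both reads of a pair separately would give such a pattern, but the sources do not state how pairs were counted. Intervals from counting error alone would then be too narrow, so every comparison between the groups used the replicate spread, and a run with the counts halved was added.

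Library totals were 33342775 to 33979479 counts. Between 17773 and 17863 genes had a count in static and between 17552 and 17620 in shear libraries. Fn1 had the largest share of counts in each library, 0.86% to 0.96%. To look for a library deposited more than once, the counts of each pair of replicates were compared; chi-square over degrees of freedom was 5.61 to 8.25, and no pair was treated as 1 library. The first principal component of log2 CPM, with 41.8% of the variance, was followed by one with 16.1%.

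Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr (minimum count 10), libraries scaled with TMM factors (1.006 to 1.026 in static, 0.979 to 0.989 in shear libraries), and the groups compared with the two-sided quasi-likelihood test (glmQLFit, glmQLFTest) without covariates. Adjusted p-values are Benjamini-Hochberg values over the 13945 genes tested, and 0.05 was the threshold. At an unadjusted p under 0.05, 4102 genes passed. CPM values use the TMM-scaled totals. Fold changes are shear over static on the log2 scale. The SE of a gene's fold change was worked back from its test. It is the absolute log2 fold change over the square root of the quasi-likelihood F statistic. The biological coefficient of variation was 5.45%.

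In all, 36 gene lists were fixed before the data were examined, 27 of pathways and 9 of other cell types. Of these, 34 had the 3 tested members needed for a list test. Lists were compared with all other tested genes by camera (limma 3.58.1, preset correlation 0.01), adjusted over the 34 lists. Camera called 14 lists, 10 higher and 4 lower, and with an estimated correlation 2 of them held, immediate early genes and cholesterol synthesis. Counts of changed members were also adjusted over the list alone; in the 24 lists for which the report gives no second count, both counts were the same. Symbols that were not matched, such as Col1a2, Nos2 and Pecam1, were not used here.

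The genes the text names follow a rule also fixed before the data were examined. It takes the 12 genes with the largest rise and the 12 with the largest fall among those with adjusted p under 0.05, a mean log2 CPM of at least 1, groups that do not overlap and no placeholder symbol; 14 genes named in advance whatever their result (among them Yap1, Wwtr1, Ccn1, Ccn2, Ankrd1, Prg4, Col2a1, Acan, Sox9 and Adamts5); and up to 4 changed members of each list with a mean log2 CPM of at least 1. Genes with placeholder symbols made up 1860 of those tested, of which 93 rose and 97 fell. Genes outside the rule are marked so in the report. In the closing section, Tnnt2, Klhl41 and the fatty acid and ERK genes come from lists written before their values were seen, except Dusp6 and Epha4. The Rgs genes and Myh4 were chosen after. Some genes that the rule selects are not reported here, though they count in the totals.

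The test was checked on simulated counts for the shear against static comparison, with 13778 genes tested. Of 50 genes changed by each of 4 sizes, it recovered 56% at a log2 fold change of 0.3, 84% at 0.5 and 100% at 1 and at 2. It called 0.11% of unchanged genes, and 7.61% of its calls were false. A moved gene set was called, as was 1 of the 34 lists, whose members had not been kept out of the changed genes. Counts were drawn for each gene on its own, so correlation between genes was not simulated. All changed genes had a log2 CPM of at least 1. They were a far smaller share of genes than the 18.5% called in the data, so these rates may differ there.

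The alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, no filter and a stricter filter (1 CPM), each library left out in turn, the replicate number as a block, and for lists camera with an estimated correlation and fry. After seeing the data, halved counts and library totals without scaling factors were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.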

Results

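RNA was sequenced from primary rat cells of the superficial layer of articular cartilage, the layer that faces the joint fluid and makes lubricin. The cells had been kept at 0 dyne/cm² (static, 3 libraries) or under fluid shear stress of 20 dyne/cm² (shear, 3 libraries). Shear stress is the drag that flowing fluid exerts on a cell surface. Each library held between 33342775 and 33979479 counts over 32161 genes, and 13945 genes had enough counts to be tested. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical. The comparison asks which transcripts differ between sheared and static cells, and the title of the series points it at the Hippo pathway and its effector YAP.

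Immediate early genes and cholesterol synthesis genes were higher under shear. By camera with its preset correlation inflammatory genes were also higher, and cell cycle, p53 target and BMP target genes lower, with adjusted p from 0.051 to 0.15 when the correlation was estimated. In all, 1508 genes were higher and 1075 were lower under shear (edgeR adjusted p under 0.05), 18.5% of the genes tested. Most changes were small. The median absolute log2 fold change of the changed genes was 0.33, and 96 genes rose and 93 fell by 2-fold or more. Among changed genes with a mean log2 CPM of at least 1, non-overlapping groups and no placeholder symbol, the steepest rise was that of Olr1. This gene encodes the lectin-like receptor for oxidised low-density lipoprotein (chromosome 4, 163239849 to 163261958 in the coordinates of the count table). It went from 2.71 ± 0.42 CPM in static to 20.9 ± 1.5 CPM in shear libraries (SD, n = 3 each), a log2 fold change of 2.95 ± 0.11 (SE). Tfpi2, a secreted serine protease inhibitor, rose from 83.4 ± 4.2 to 406 ± 9 CPM (SD, n = 3 each), a log2 fold change of 2.28 ± 0.05 (SE, edgeR adjusted p = 2.4e-20). The zinc-finger transcription factors Egr2 and Egr1 rose by 2.46 and 1.97 on the log2 scale. Gldn, which encodes the extracellular protein gliomedin, rose by 2.46. The other genes with the steepest rises were Msh5 (2.31), Sema7a (1.86), the G-protein regulator Rgs16 (1.55), the calcineurin regulator Rcan1 (1.55), the choline transporter Slc5a7 (1.53), the kinase Plk3 (1.49) and the cytokine Il6 (1.46).

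Among genes ranked in the same way, the steepest fall was that of Myh3, the embryonic myosin heavy chain (chromosome 10, 53621375 to 53645194 in the table's coordinates). Myh3 went from 21.9 ± 0.1 to 1.68 ± 0.11 CPM (SD, n = 3 each), a log2 fold change of -3.71 ± 0.11 (SE, edgeR adjusted p = 1.1e-17). Dact1, a regulator of Wnt signalling, went from 19.6 to 5.52 CPM (log2 fold change -1.83), and Irs1, the insulin receptor substrate, from 17.2 to 5.13 CPM (-1.75). The transcription regulators Osr1 (-1.74), Patz1 (-1.71), Dmrt2 (-1.51) and Id1 (-1.48) were also among the 12 steepest falls. The others were Fam46b (-1.87), Spata13 (-1.61), Ankrd1 (-1.37), the fast troponin Tnnc2 (-1.36) and the olfactory receptor gene Olr1387 (-1.23). Skeletal muscle markers fell beside Myh3 and Tnnc2: of 5 tested, 0 rose and 3 fell, with a median log2 fold change of -0.68 (camera adjusted p = 0.017, and adjusted p = 0.15 with an estimated correlation). Without the low-count filter the median was -0.16 (camera adjusted p = 0.043). The markers that fell were Tnnt3 (-0.68) and, at low levels and named after their values were seen, Acta1 (-1.26) and Mylpf (-1.69). The most abundant of the 5, Myh4, also named after its value was seen, had a log2 fold change of 0.10 ± 0.08 (SE, edgeR adjusted p = 0.47).

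Many single genes separated the groups. In 4556 of the genes tested (32.7%) all libraries of one group lay above all of the other, where the average over all such splits is about 10%. Genes of a library can vary together, so a single split can exceed 10% by chance. Separation under the other splits was not counted. The balance of rises and falls depended on the scaling: upper-quartile factors gave 1275 higher and 1364 lower genes, and library totals alone gave 1124 higher and 1730 lower.

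**Figure D1:**
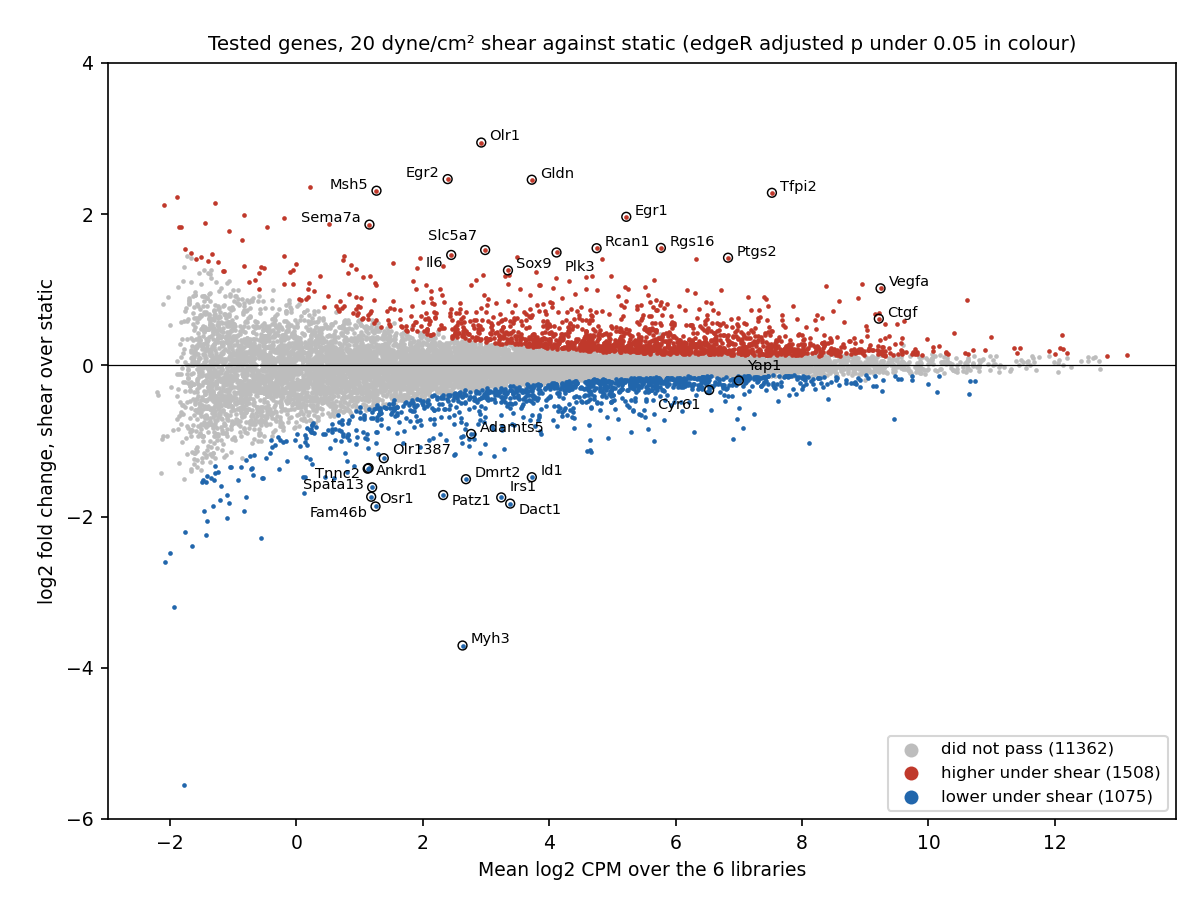
Each point is 1 of 13945 tested genes, with its mean log2 CPM over the 6 libraries on the horizontal axis and its log2 fold change (shear over static) on the vertical axis. The 1508 red genes were higher and the 1075 blue genes lower under shear, and circles mark named genes, from Olr1 at 2.95 to Myh3 at -3.71.

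Genes of the Hippo pathway, a kinase cascade that restrains the co-activators YAP and TAZ, changed in both directions. Of 32 components, all tested, 4 rose and 8 fell (7 and 9 adjusted over the list alone). Yap1 itself (chromosome 8, 6135493 to 6203579 in the table's coordinates) went from 137 ± 3 to 119 ± 2 CPM (SD, n = 3 each), a log2 fold change of -0.20 ± 0.05 (SE, edgeR adjusted p = 0.0028). Wwtr1, which encodes TAZ, had a log2 fold change of -0.04 ± 0.08 (SE, edgeR adjusted p = 0.82), and the kinase gene Lats2 one of 0.01 ± 0.04 (SE, edgeR adjusted p = 0.87). The LIM-domain gene Ajuba fell furthest, from 37.4 CPM in static libraries, with a log2 fold change of -1.14. Vgll3 (-0.49), the YAP-binding scaffold gene Amot (-0.48) and its relative Amotl2 (-0.19) fell too. Vgll4, a competitor of YAP for TEAD transcription factors, rose by 0.70. Outside the naming rule, Lats1 (0.33), Mob1b (0.34) and Taok1 (0.17) rose, and Stk4 (-0.32), Tead4 (-0.44) and Ptpn14 (-0.36) fell. These were named after their values were seen. The list as a whole had a median log2 fold change of -0.01 (camera adjusted p = 0.14).

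Target genes of YAP and TAZ, taken from a published signature that was not chosen on these libraries, also split. Of 21 tested, 8 rose and 7 fell (8 and 8 adjusted over the list alone). Ctgf, the connective tissue growth factor gene now called Ccn2, rose from 480 ± 4 to 736 ± 42 CPM (SD, n = 3 each), a log2 fold change of 0.62 ± 0.05 (SE, edgeR adjusted p = 3.8e-10). Cyr61, now called Ccn1 and from the same family, fell from 103 ± 2 to 82.5 ± 2.2 CPM (SD, n = 3 each), a log2 fold change of -0.33 ± 0.05 (SE, edgeR adjusted p = 2.0e-05). Ankrd1, the ankyrin repeat gene often used as a YAP readout, fell by 1.37 on the log2 scale, from 3.45 to 1.33 CPM. The kinase gene Nuak2 (1.18), Fjx1 (0.86) and the tissue factor gene F3 (0.70) rose. The list had a median log2 fold change of 0.02 (camera adjusted p = 0.14). The lists share 3 genes, Lats2, Amotl2 and Ptpn14 (outside the naming rule). The median of the target list changed sign with upper-quartile factors (-0.0025) and with library totals alone (-0.026), and that of the Hippo list without static replicate 2 (0.0018) and without shear replicate 3 (0.019). Camera called the target list without the low-count filter (adjusted p = 0.047) and the Hippo list with library totals alone (adjusted p = 0.049).

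**Figure D2:**
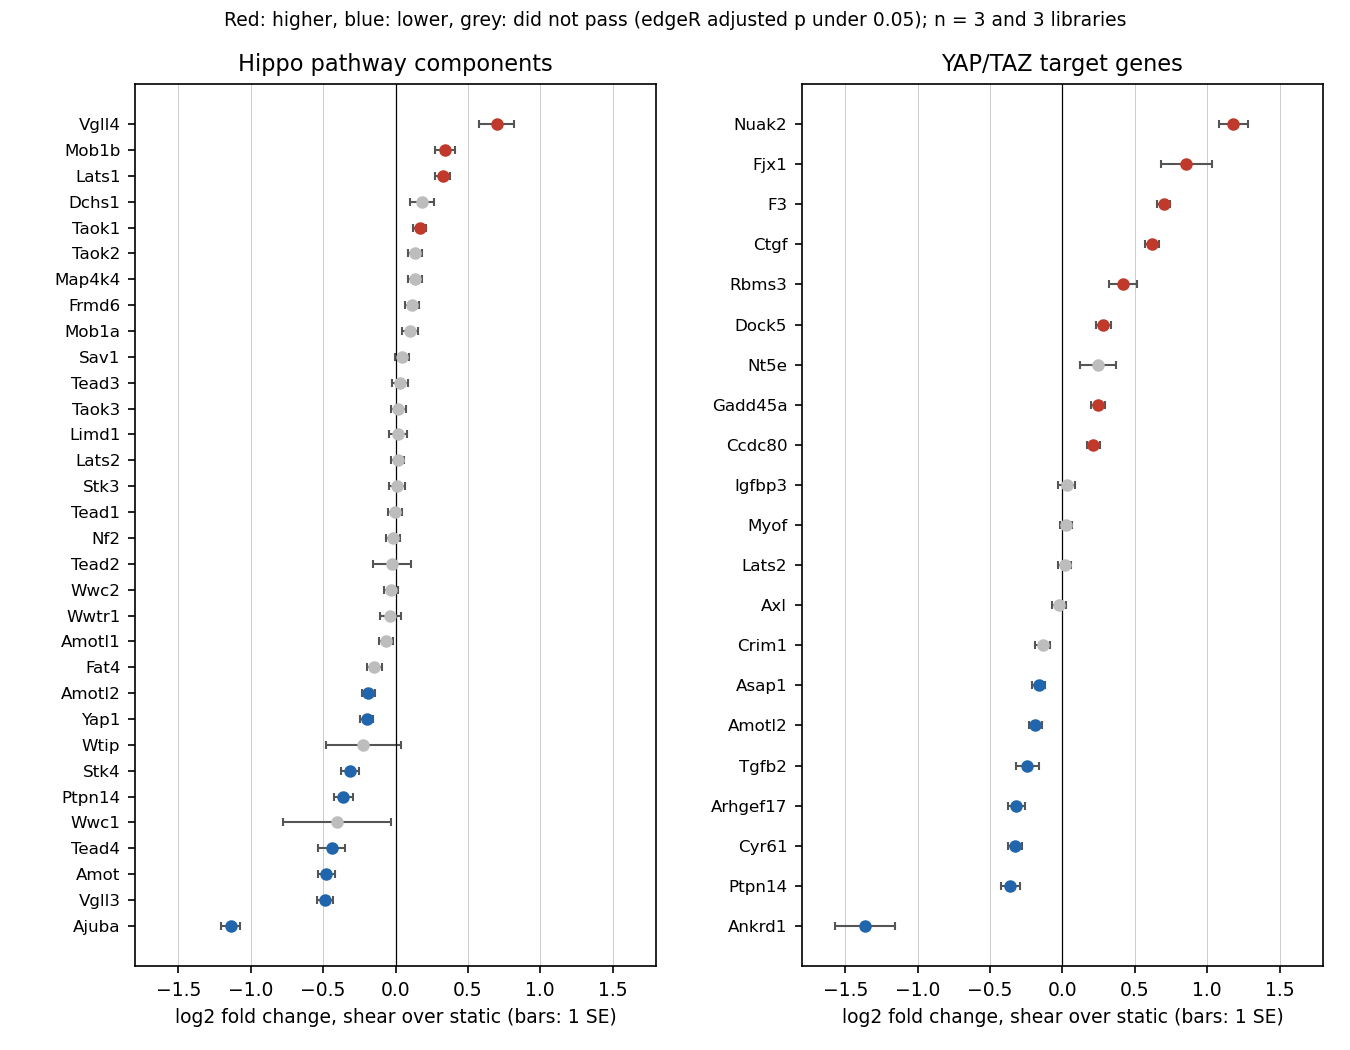
Log2 fold change (shear over static, horizontal axis) of the 32 tested Hippo pathway components on the left and the 21 tested YAP/TAZ target genes on the right; points are estimates from 3 libraries per group and bars 1 SE. In both lists genes lie on either side of 0, from Ajuba (-1.14) to Vgll4 (0.70) and from Ankrd1 (-1.37) to Nuak2 (1.18).

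Other lists tied to mechanical force moved little as lists. Of 15 actin cytoskeleton genes driven by the transcription factor SRF, Fhl2 rose (0.25) and Tgfb1i1 fell (-0.28), and the list had a camera adjusted p of 0.79. Of 24 integrin and focal adhesion genes 4 rose, with paxillin (Pxn, 0.68) and the fibronectin receptor subunit Itga5 (0.30) the furthest, and 2 fell (camera adjusted p = 0.36). Those that fell were Bcar1 (-0.23) and, at a low level and named after its value was seen, the integrin gene Itgb8 (-2.48). Of 13 genes for mechanosensitive channels and force transmission, the channel gene Piezo2 rose (0.42, camera adjusted p of the list 0.79). Of 9 genes known to respond to flow in endothelium 3 rose and 3 fell (camera adjusted p = 0.79). Among these the haem oxygenase gene Hmox1 rose by 0.89, and the endothelin gene Edn1 and the cytochrome gene Cyp1b1 had log2 fold changes of -0.97 and -0.35.

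Among genes that define cartilage, Sox9 and Acan went in opposite directions. Sox9, the transcription factor of chondrocyte identity, rose from 6.54 ± 0.26 to 15.6 ± 0.4 CPM (SD, n = 3 each), a log2 fold change of 1.26 ± 0.09 (SE, edgeR adjusted p = 1.8e-10). Acan, the gene of the cartilage proteoglycan aggrecan, fell from 14.2 ± 0.6 to 11.3 ± 0.6 CPM (SD, n = 3 each), a log2 fold change of -0.34 ± 0.09 (SE, edgeR adjusted p = 0.0065). These were the changes among 14 tested cartilage matrix genes and SOX regulators; the list's median was -0.22 while camera pointed up (adjusted p = 0.80). Col2a1, the main cartilage collagen gene, had 4 to 8 counts per library and was too low to test. Of 5 tested superficial zone markers 3 rose and 1 fell (camera adjusted p = 0.36). Abi3bp rose by 0.41, and the lubricin gene Prg4 rose from 18.8 ± 1.4 to 22.4 ± 0.9 CPM (SD, n = 3 each), a log2 fold change of 0.25 ± 0.07 (SE, edgeR adjusted p = 0.018). The call of Prg4 ended without static replicate 1 (edgeR adjusted p = 0.055), static replicate 3 (0.096) or shear replicate 3 (0.071), and with library totals alone (0.062).

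The list of fibrous collagens and collagen processing was higher by camera: of 27 tested, 7 rose, 0 fell and 20 did not pass (10 and 0 adjusted over the list alone), with a median log2 fold change of 0.07 (camera adjusted p = 0.015, and adjusted p = 0.24 with an estimated correlation). No collagen gene was among those that rose. The furthest were the collagen cross-linking enzyme gene Lox (0.38), lumican (Lum, 0.32), tenascin C (Tnc, 0.22) and periostin (Postn, 0.21). The call of the list ended with library totals alone (camera adjusted p = 0.071). Of 20 enzymes that degrade matrix, 0 rose and 4 fell (0 and 5 adjusted over the list alone), and the list had a camera adjusted p of 0.22. Adamts5, an aggrecan-cleaving protease gene, fell from 9.26 ± 0.49 to 4.94 ± 0.77 CPM (SD, n = 3 each), a log2 fold change of -0.91 ± 0.12 (SE, edgeR adjusted p = 4.1e-06). The collagenase gene Mmp13 had a log2 fold change of 0.09 ± 0.11 (SE, edgeR adjusted p = 0.66), and the stromelysin gene Mmp3 one of 0.05 ± 0.05 (SE, edgeR adjusted p = 0.63). Of 7 tested genes of chondrocyte hypertrophy, the growth step before cartilage turns to bone, 2 rose and 1 fell. Runx2 (1.06) and Vegfa (1.02) rose and Mef2c fell (-0.65), with a list median of 0.09 (camera adjusted p = 0.0058, and adjusted p = 0.12 with an estimated correlation). With limma-voom the hypertrophy list had an adjusted p of 0.17, and without the low-count filter its median was -0.00078. Its median was 0.17 without static replicate 1, 0.16 without static replicate 2 or shear replicate 1, 0.057 without static replicate 3 and 0.053 without shear replicate 3, each with its call kept.

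Immediate early genes, transcribed within minutes of a stimulus, rose as a list. How long the cells were sheared and when RNA was taken are not given in the sources used here. Of 16 tested, 10 rose and 4 fell (11 and 4 adjusted over the list alone), with a median log2 fold change of 0.54 (camera adjusted p = 5.0e-16, and adjusted p = 0.014 with an estimated correlation). Besides Egr1 and Egr2, Junb rose by 1.41 and Fosb by 1.11. The members that fell, named after their values were seen, were the phosphatase gene Dusp1 (-0.91) and the nuclear receptor genes Nr4a1 (-0.51), Nr4a2 (-0.60) and Nr4a3 (-0.50). Inflammatory mediators were higher as a list: of 19 tested, 10 rose and 2 fell, with a median of 0.24 (camera adjusted p = 2.4e-10, and adjusted p = 0.051 with an estimated correlation). Ptgs2, the inducible cyclooxygenase gene, rose from 69.4 CPM by 1.42 on the log2 scale, the chemokine gene Ccl2 by 1.08 and the cytokine gene Lif by 1.04. The members that fell, named after their values were seen, were Cxcl1 (-0.25) and the NF-kappaB inhibitor gene Nfkbia (-0.34). Of 13 interferon-stimulated genes, Mx1 rose (0.83, camera adjusted p of the list 0.91).

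Cholesterol synthesis genes rose as a list. Of 22 tested, 16 rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 fold change of 0.31 (camera adjusted p = 7.2e-21, and adjusted p = 0.014 with an estimated correlation). Insig1, which encodes a sterol-sensing regulator of the pathway, rose by 0.90, and the enzyme genes Idi1 and Msmo1 rose by 0.88 and 0.75. Of 17 antioxidant targets of NRF2, 7 rose and 0 fell, with a median of 0.12 (camera adjusted p = 5.4e-05, and adjusted p = 0.051 with an estimated correlation). Hmox1 (0.89), the cystine transporter gene Slc7a11 (0.71) and the thioredoxin reductase gene Txnrd1 (0.58) led that list, whose median was 0.076 without static replicate 1. Of 26 glycolysis and HIF target genes, 6 rose and 1 fell, with a median of 0.10 (camera adjusted p = 9.1e-05, and adjusted p = 0.12 with an estimated correlation). The members that rose include Vegfa and the hexokinase gene Hk2 (0.79), and Bnip3 and Kdm3a rose by 0.48 and 0.49. Of 19 genes of the unfolded protein and integrated stress responses, 7 rose and 1 fell (7 and 2 adjusted over the list alone), led by Atf3 (0.83) and Chac1 (0.69). Their median was -0.03 while camera pointed up (adjusted p = 0.077). Of 12 heat shock genes 4 rose and 2 fell (camera adjusted p = 0.30), with the co-chaperone gene Bag3 (0.45) the furthest. Of 18 autophagy and lysosome genes 2 rose and 0 fell, with Gabarapl1 at 0.26, and the list had a camera adjusted p of 0.79.

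Genes of the cell cycle and DNA replication were lower as a list. Of 28 tested, 0 rose and 14 fell (0 and 18 adjusted over the list alone), with a median log2 fold change of -0.17 (camera adjusted p = 5.4e-06, and adjusted p = 0.051 with an estimated correlation). Examples were the thymidylate synthase gene Tyms (-0.48), the replication helicase gene Mcm2 (-0.40), Bub1b (-0.28) and Rrm2 (-0.26). Targets of p53 and cell cycle inhibitors were also lower as a list. Of 14 tested, 2 rose and 9 fell, with a median of -0.31 (camera adjusted p = 1.1e-05, and adjusted p = 0.074 with an estimated correlation). The kinase gene Plk2 fell from 395 CPM by 1.02 on the log2 scale, Tp53inp1 by 0.75 and Cdkn1a, the gene of the cell cycle inhibitor p21, by 0.72. Gadd45a, named after its value was seen, was among the 2 members that rose (0.25).

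The list of TGF-beta ligands and targets was higher by camera and that of BMP ligands and targets lower, with members of each going the other way. Of 14 tested TGF-beta genes 7 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 3.3e-05, and adjusted p = 0.051 with an estimated correlation). The cytokine gene Il11 (0.73), the co-repressor gene Ski (0.64) and Ctgf (0.62) led the list. Of 14 tested BMP genes 2 rose and 5 fell, with a median of -0.28 (camera adjusted p = 6.6e-05, and adjusted p = 0.15 with an estimated correlation). Of the ID family of transcription inhibitors, Id1 (-1.48), Id2 (-0.999) and Id3 (-0.82) fell, while the ligand gene Bmp2 rose (0.60). Of 14 Wnt targets and modulators 4 rose and 2 fell (camera adjusted p = 0.096). Lef1, a transcription factor of the Wnt pathway, rose by 1.18 and the ligand gene Wnt5b by 1.12.

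**Figure D3:**
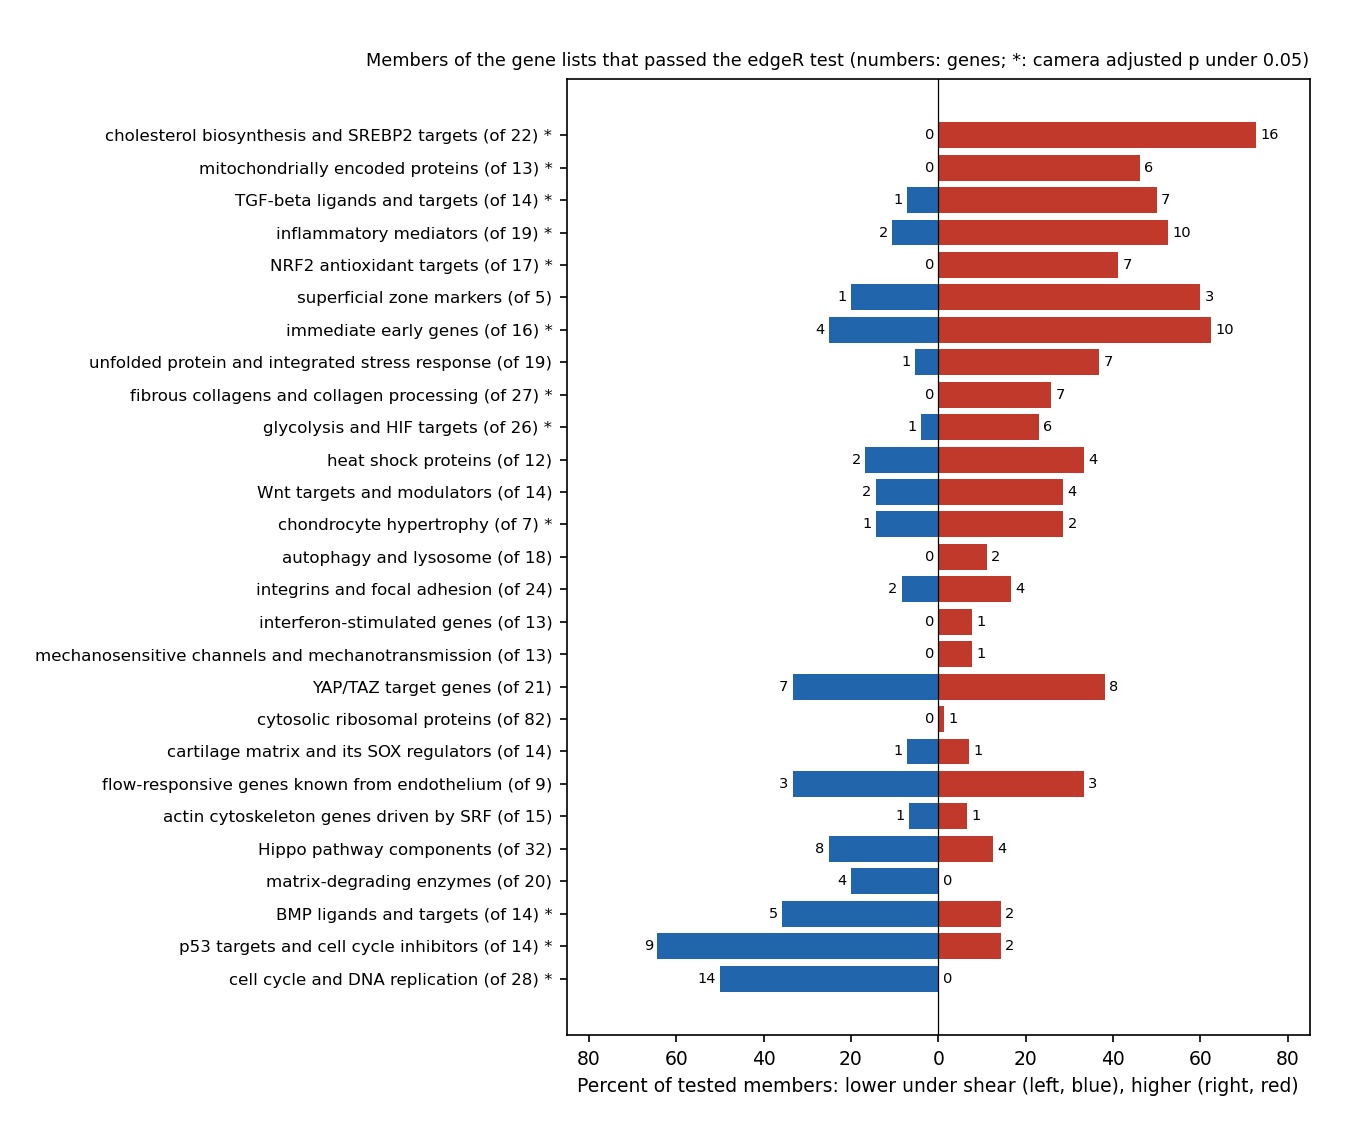
Percent of the tested members of each pathway list that were higher (red, right) or lower (blue, left) under shear, with the number of genes at each bar and the number tested in brackets; an asterisk marks a camera adjusted p under 0.05. Lists are ordered by the percent higher minus the percent lower, from cholesterol synthesis (16 of 22 higher, 0 lower) at the top to the cell cycle (0 higher, 14 of 28 lower) at the bottom.

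Markers of other cell types gave little beyond the muscle markers. Of 5 tested osteoblast and osteocyte markers 2 rose and 0 fell, with a median of 0.63 (camera adjusted p = 0.031, and adjusted p = 0.20 with an estimated correlation). The members that rose were Runx2, which the hypertrophy list also holds, and at a low level Dmp1 (1.41), named after its value was seen. The median of that list was 1.04 without static replicate 2. Its call ended without static replicate 1 (median 0.47, camera adjusted p = 0.084), with DESeq2 (0.064), with limma-voom (0.061) and without the low-count filter (0.062). Of 9 fibroblast markers 1 rose and 2 fell (2 and 2 adjusted over the list alone), with Cdh11 at -0.29 (camera adjusted p = 0.98). Of 4 endothelial markers Kdr fell (-0.98, camera adjusted p of the list 0.24). Of 4 macrophage and 3 adipocyte markers tested 0 passed the edgeR test (camera adjusted p = 0.79 for each list), and of 6 pericyte and smooth muscle markers 0 rose and 1 fell (camera adjusted p = 0.79). A single erythroid marker, the haemoglobin gene Hba-a3 (-1.25, named after its value was seen), and a single Schwann cell marker, Prx (-0.48), could be tested, and both fell.

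Ribosomal protein genes moved little, with 1 of 82 higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.16). Of 13 mitochondrially encoded protein genes 6 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.015, and adjusted p = 0.57 with an estimated correlation). The mitochondrial share of counts was 2.26% to 2.40% in static libraries and 2.35%, 2.69% and 2.40% in shear libraries. Without shear replicate 2, which had the highest share, the median of these genes was 0.06 (camera adjusted p = 0.21).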

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

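Halved counts and library totals without scaling factors were chosen after seeing the data, and the other settings before. The count of genes higher under shear (1508) stayed within 1.5 times under all 15 alternatives, from 1124 to 1611; leaving out 1 library gave 1193 to 1469. The count of lower genes (1075) was 1364 with upper-quartile factors and 1730 with library totals alone, and 769 to 948 with 1 library left out. The share of higher among changed genes was 58.4%, against 48.3% with upper-quartile factors and 39.4% with library totals alone. These moved the median log2 fold change of all genes by -0.026 and -0.050. DESeq2 called 2367 genes, 2338 of them shared with the 2583 of edgeR, and limma-voom 2539 (2511 shared). Halved counts gave 2602 genes (2538 shared). The YAP/TAZ target list had a median of -0.0025 with upper-quartile factors and -0.026 with library totals alone, 0.030 without the low-count filter (camera adjusted p = 0.047), and 0.016 to 0.034 with 1 library left out. The Hippo list had a median of -0.062 with library totals alone (camera adjusted p = 0.049) and from -0.016 to 0.019 with 1 library left out, above 0 without static replicate 2 (0.0018) or shear replicate 3 (0.019). Fry, which does not compare a list with other genes, gave adjusted p = 0.0036 for the target list (median 0.024) and 0.0020 for the Hippo list (median -0.012). The hypertrophy list had a median of -0.00078 without the low-count filter. That setting also moved the median of the muscle markers to -0.16 and of the BMP list to -0.43. Library totals alone lowered the medians of fibrous matrix (0.024), hypertrophy (0.039), glycolysis and HIF (0.050), NRF2 (0.071), TGF-beta (0.095) and mitochondrial genes (0.099) by over 1.5 times, and upper-quartile factors that of fibrous matrix (0.047). Of 14 called lists, 2 kept their call under all alternatives and 12 lost it under at least 1, each of them with the estimated correlation. Of 121 genes selected by the naming rule and with values, 105 kept direction and side of the threshold throughout. Direction changed in 3, none of them called: Wwtr1 without static replicate 2 (0.014) or shear replicate 3 (0.018), Lats2 with upper-quartile factors (-0.011), library totals alone (-0.035) or without shear replicate 2 (-0.0034), and Mmp3 with library totals alone (-0.0037). The call was lost under at least 1 alternative in 13 genes, among them Adamts1, Cdkn2a, Creb5, Cryab, Itga1, Pdgfra, Pdgfrb, Prg4, Rps20, Sfrp1, Thbd and Thbs4. The cause of these changes was not tested. Nothing in the values pointed to pairing by replicate number, and the labels do not state any. The deviations of same-numbered libraries correlated at -0.10, -0.25 and 0.06 across genes, and not every library correlated best with its own number. The highest value was 0.30, for static replicate 2 with shear replicate 1, and pairing in another order was not tested. With the replicate number as a block, 1372 genes were higher and 964 lower, 2306 of them shared with the 2583 of the fit without it. At this depth and replicate spread, 56% of simulated changes of 0.3 on the log2 scale were recovered over 13778 genes. The simulation changed far fewer genes than the 2583 called here, all with a log2 CPM of at least 1, so recovery in the real data may differ. Depth was not varied on its own.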

Other observations

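Some tests in this part were chosen after the results were seen. They are the splits of the libraries, the family scan, the receptor sums without Olr1387 and every comparison of muscle with receptor genes. The other tests were written before their results. For the fatty acid and ERK lists the prediction was a camera p under 0.05. For the second muscle list it was a median log2 fold change of -0.68 or less. All were met. The estimated correlation and the fold change of Myh4, which leave these explanations open, were not in the predictions.

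Genes with the stem Rgs, mostly regulators of G-protein signalling, were the only one of 368 gene families, formed by shared symbol stems with at least 5 tested members, that camera called (adjusted p = 0.0040, and unadjusted p = 0.0099 with an estimated correlation, where 0 families passed adjustment). Of 11 tested genes 4 rose and 1 fell. Rgs16 rose by 1.55 on the log2 scale, Rgs3 by 0.71, Rgs2 by 0.65 and Rgs7bp by 0.21, and Rgs12 fell (-0.23). The regulators shorten the signal of G-protein coupled receptors, while Rgs7bp encodes a protein that binds one of them and was taken in by its symbol. The median of the family was 0.03.

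The rise of cholesterol synthesis genes raised the hypothesis of an SREBP response that takes in fatty acid synthesis. Of 12 tested fatty acid synthesis genes 3 rose and 0 fell: Fasn (0.35), Scd2 (0.33) and Scd (0.30). Their median log2 fold change was 0.11 and camera gave p = 0.040, but p = 0.096 with an estimated correlation, so a wider response may exist and was not settled. The rise of immediate early genes raised the hypothesis of higher output of the ERK pathway. Of 10 ERK output genes 4 rose, Dusp6 (1.15), Spry4 (0.73), Spry2 (0.39) and Phlda1 (0.37), and Epha4 fell (-1.07). Camera gave p = 0.0057, but p = 0.21 with an estimated correlation, and the median was 0.06; Dusp6 and Epha4 had been seen before the list was made. This also stays open.

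YAP/TAZ target genes changed in both directions. The trend of fold change with abundance was small beside these changes. The median log2 fold change was -0.13 in the lowest 10% of genes by abundance and 0.03 in the highest 10%. Members of the list ran from -1.37 (Ankrd1) to 1.18 (Nuak2). After the trend was removed, 8 members remained higher and 7 lower by more than 2 standard errors. The same numbers, 8 and 7, remained after removing a trend with gene length, which was also weak (Spearman correlation 0.04 across genes). Removing trends this small could change little, so the kept counts exclude nothing by themselves. No biological explanation was tested, and whether YAP/TAZ activity or several inputs moved these genes stays open.

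Skeletal muscle genes fell. Fewer muscle cells in the sheared cultures is a candidate explanation: 11 tested members of a second muscle list had a median log2 fold change of -0.74, with 0 higher and 7 lower (camera p = 2.4e-06, and p = 0.0087 with an estimated correlation). The most abundant of its changed members, Tnnt2, went from 13.4 to 8.66 CPM (log2 fold change -0.63 ± 0.10, SE), and Tnnt3 of the first list from 6.65 to 4.16 CPM. With Myh3 at -3.71 ± 0.11 (SE) the muscle genes did not fall by a common factor. Myh4, the most abundant marker of the first list, goes against fewer muscle cells at 0.10 ± 0.08 (SE, edgeR adjusted p = 0.47), so this explanation stays undecided. Whether a lower background of reads from untranscribed loci was the whole cause depended on Olr1387, a changed gene that carried the olfactory and vomeronasal receptor sum. Without Olr1387, Tnnt3, the changed marker of the first list with the smallest fall, fell further than that sum by -0.59 ± 0.21 (SE, log2 scale). With Olr1387 the difference was -0.19 ± 0.18 (SE). For Klhl41 of the second list, the changed muscle gene with the smallest fall, these were -0.53 ± 0.21 and -0.13 ± 0.18 (SE). Olr1387 was left out after its own fall was seen, so these values do not decide the question. The 10 changed muscle genes of both lists lost at least 0.41 CPM each. Of them 8 lost more than the 0.86 CPM of the highest of the other 1250 receptor genes in static libraries. Against Olr1387, at 3.93 CPM in static libraries, only Tnnt2 did (4.71 CPM lost). These 10 genes were picked by their fall, so their losses do not test the background. The other 1250 receptor genes together lost 0.29 CPM, while with Olr1387 the sum went from 8.89 to 6.35 CPM. Lower transcription in the cartilage cells themselves was not tested.

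Low-abundance genes lay lower under shear, with a median log2 fold change of -0.13 in the lowest 10% of genes by abundance and 0.03 in the highest 10%, and more genes had a count in each static than in each shear library. Library totals do not account for it, as they were already close, and the highest, 33979479 counts, was that of shear replicate 3. Thinning to 33342775 counts could therefore change little. The gap between the lowest static and the highest shear library was 148 genes after it, against 153 before. A lower background of reads from untranscribed loci may contribute. The summed CPM of 1251 receptor genes had a shear to static ratio of 0.71 ± 0.06 (SE). It was lower in every shear than in every static library. That met the prediction written before, which asked for such a separation and a ratio of 0.9 or less. But 1 gene, Olr1387, carried the sum, and without that gene the ratio was 0.94 ± 0.11 (SE). Olr1387 was left out after the results were seen, and the background stays undecided. A biological fall of weakly expressed genes under shear stays open and untested.

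The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 1508 higher and 1075 lower genes, and 1 split in all gave as many in either direction. The highest of the other 9 splits was 0 by edgeR, with 238 to 530 genes at an unadjusted p under 0.05. Each of those 9 put static and shear libraries in both groups, so a difference between the 2 conditions would widen the spread within groups. Few calls there follow from that mixing and are no support for the real split.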
